A study of Arabidopsis thaliana with 8 samples.

How the data were processed

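Whole Arabidopsis thaliana seedlings, 12 days old, of 4 genotypes were compared on 8 arrays, 2 per genotype, grouped by the sample titles. Per the labels, plants grew on MS medium at 22 °C with 16 h of light and 8 h of dark, RNA was extracted with TRIzol and labelled with Cy3, and each array carried 1 sample. The authors deposited the scanner output of each array and a table of processed values. The intensity of a spot, gProcessedSignal, was made per the file headers with Agilent Feature Extraction 10.5.1.1, with spatial and multiplicative detrending on and background correction off. Its median differed between arrays, from 835 to 1308, so it was not taken as normalized between them. The submitters' processing notes name version 9.1 of that program, so the 2 sources differ. The deposited table holds log2 values whose distribution is the same on every array, with a median of 10.1 for each of wild type, asf1a, asf1b and asf1ab replicates 1 and 2. Their correlation with log2(gProcessedSignal) of the same array was 0.996 to 0.999 across 43603 probes, so its scale and direction were read from the values as log2 and quantile normalized, and the software is not given in the sources used here. Detection flags, 0 or 1 per spot, were used as deposited.

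The main values were log2(gProcessedSignal) minus the array's 75th percentile. Control spots were left out, spots of a probe were averaged, and 48 probes with outlier spots were left out (100 spots on any array), with 0 saturated spots. Of 43603 probes, 35964 had 1 locus, 446 several and 7193 none, and only those with 1 were used. Of these, 34057 were named by RefSeq accession through a reference table (assembly TAIR10.1), used for names alone, 1904 by a locus in the files and 3 by an organelle locus. The probes covered 26249 loci, and 26224 genes had a usable probe. A gene took its brightest probe by mean signal and was tested if that probe was well above background on both arrays of at least 1 genotype, which left 22301 genes, 19474 of them measured on all 8 arrays. None of the coordinates of that assembly were used, and neighbouring loci were ordered by locus number. Probes were not matched to a genome, which was not given in the sources used here, and the 2 target positions are those of the files.

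Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), 8 arrays and 4 genotypes in 1 fit, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The residual degrees of freedom were 4 and the prior added 2.40. The comparisons were each mutant label against wild type, asf1ab against each single-mutant label, and the non-additive contrast. A gene well above background on neither array of a genotype has only a bound there. Its fold is given as at least the brighter genotype's mean over the dimmer one's, each dim array taken at the higher of its lowest signal well above background and the probe's own signal, and the adjusted p is that of the fit. The R package data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were also used.

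The comparisons, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took, for each mutant against wild type, the 12 highest and 12 lowest log2 changes among genes past the threshold and the 5 highest and 5 lowest for the other contrasts. In comparisons of 2 genotypes, all values of 1 had to lie above all values of the other. For each list it took up to 4 members past the threshold with the largest change, or the member with the lowest p where none passed. Because it named many genes at the detection limit, the same rule was also applied to genes measured on all 8 arrays, which was chosen after the data were seen. Genes named in the text follow these rules, except where the other observations say otherwise, and for brevity not every one is given. The fixed lists were DNA damage response, DNA replication and S phase, mitosis, core histones, histone variants and chaperones, DNA methylation and silencing, heat shock, salicylic acid, jasmonate, rapid stress response, abscisic acid with drought and cold, photosynthesis, flavonoid, glucosinolate, circadian clock, flowering, root markers, iron and phosphate starvation, auxin and reference genes. By rule, cytosolic ribosomal proteins, transposable element genes and chloroplast- and mitochondrion-encoded genes were added. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 22 lists of a comparison with at least 3 measured genes, and again with an estimated correlation.

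The steps were tested on simulated data for 22301 genes per comparison, with 67, 67 and 66 genes changed 1.5-, 2- and 4-fold. For asf1a against wild type it recovered 58.2%, 94.0% and 89.4%, with 10 false calls. For asf1b against wild type it recovered 58.2%, 92.5% and 97.0%, with 8 false calls. For asf1ab against wild type it recovered 56.7%, 94.0% and 93.9%, with 14 false calls. For asf1ab against asf1a it recovered 56.7%, 92.5% and 97.0%, with 12 false calls. For asf1ab against asf1b it recovered 67.2%, 89.6% and 100%, with 6 false calls. For the non-additive contrast it recovered 10.4%, 64.2% and 86.4%, with 6 false calls. In simulated data for asf1ab against wild type, limma's camera called a list of 25 genes shifted by 0.5 on the log2 scale and did not call an unshifted list of the same size. In all these simulations genes were drawn independently of each other, and only the stated genes changed. The rates therefore do not cover correlated genes or changes as widespread as those in the data. The alternatives were quantile normalization, median centring, a normexp background with an offset of 50, the deposited table, no filter or a filter on all 8 arrays, the mean of a gene's probes, the compared genotypes alone, an intensity trend with a robust prior, a 2-fold minimum, the replicate number or the slide as a block, and leaving out each array. A common detection floor, a filter on all 8 arrays for lists and overlaps, crossed replicate numbers and overlaps with separate wild-type arrays were added after the data were seen. The slide and scan of each array were read from the file headers, where every slide has 1 scan. Overlaps of calls were compared with independent lists, and correlations of changes with 20 simulated data sets of unchanged groups.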

Results

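Total RNA from whole 12-day-old Arabidopsis thaliana seedlings was measured on 8 single-colour Agilent arrays, 2 for each of 4 genotypes: wild type, mutants labelled asf1a and asf1b, and the double mutant asf1ab. The design compares each mutant with wild type under normal growth, on MS medium at 22 °C with 16 h of light and 8 h of dark. Each array carried 43603 probes, and 22301 genes were tested. The arrays lay on 2 slides, wild type and asf1a on slide 1 and asf1b and asf1ab on slide 2, each slide with its own scan. On slide 1, 69.5% to 69.7% of spots were well above background, and on slide 2, 79.4% to 82.8%. The lowest signal well above background was 83.1 to 100.4 on slide 1 and 12.4 to 13.8 on slide 2, so slide 2 measured dimmer transcripts. Between the 2 arrays of a genotype, the correlation across 19474 genes measured on all 8 arrays was 0.997 to 0.998. Nothing in the labels says that the duplicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

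ASF1A (AT1G66740) and ASF1B (AT5G38110) encode the Arabidopsis forms of ASF1, a chaperone that carries histones H3 and H4. The ASF1A probe was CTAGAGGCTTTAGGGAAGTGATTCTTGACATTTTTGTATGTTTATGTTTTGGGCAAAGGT, placed by the files at chromosome 1, 24897333 to 24897392, and the ASF1B probe was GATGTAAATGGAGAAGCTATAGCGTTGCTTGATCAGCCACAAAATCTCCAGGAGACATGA, at chromosome 5, 15227235 to 15227294. Both positions are on the array design's ath1:Jan2004 grid, and each probe is 60 bases long and named by the files for its gene's mRNA. The exon or untranslated region it lies in was not analysed here. Levels are log2 signals relative to the array's 75th percentile, and changes are log2 differences between genotype means ± standard error in limma (n = 2 arrays per genotype). In wild type, ASF1A was at 0.03 and 0.01 and ASF1B at -1.07 and -1.11 on the 2 arrays. On the arrays labelled asf1a, ASF1A was at -0.02 and 0.10, a change of 0.02 ± 0.07 that did not pass the test (adjusted p = 0.91). ASF1B was not well above background on either of them and was at least 31.2-fold lower than in wild type (adjusted p = 0.00038).

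On the arrays labelled asf1b the pattern was the opposite: ASF1A was at -1.58 and -1.53, 2.98-fold below wild type (-1.57 ± 0.07, adjusted p = 0.00016). ASF1B, at -1.34 and -1.17, did not pass the test there (-0.16 ± 0.27, adjusted p = 0.70). Both genes were lower in the double mutant, ASF1A by 2.75-fold (-1.46 ± 0.07, adjusted p = 2.7e-05) and ASF1B, not well above background, by at least 261-fold (adjusted p = 6.8e-06). The 2 single-mutant labels therefore went against the genes that the files name. ASF1A was low on every array of slide 2 and on none of slide 1, so its fall cannot be told apart from a difference between the slides. ASF1B fell on the arrays labelled asf1a within slide 1, so that fall is free of such a difference. All values are given for the arrays as labelled, so a direction drawn for asf1a or asf1b belongs to the arrays with that label, whichever gene they lack. Where each mutation lies relative to its probe is not given in the sources used here.

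**Figure D1:**
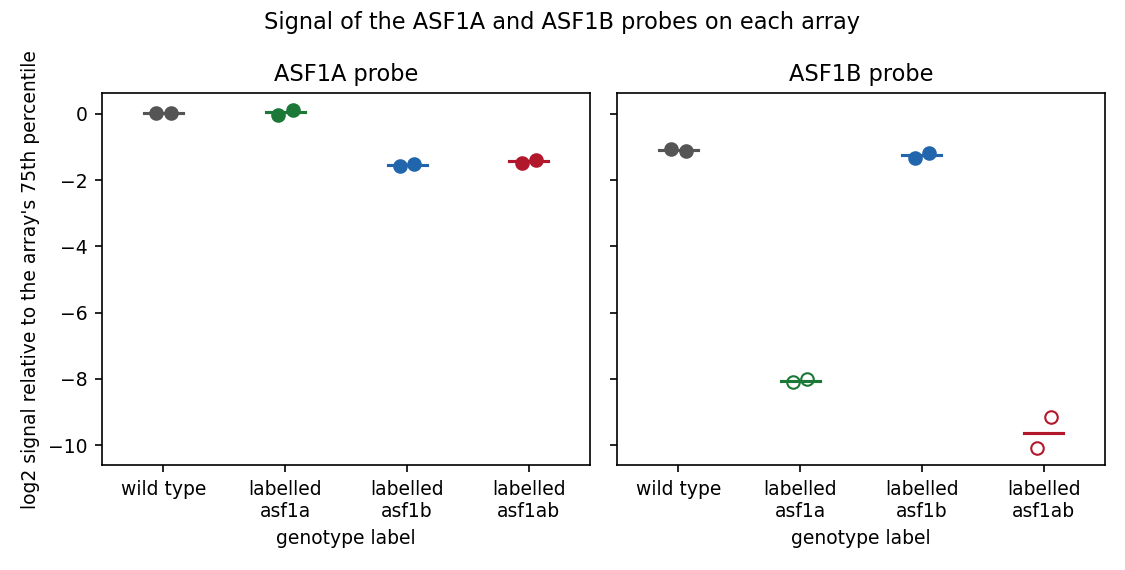
Signal of the ASF1A and ASF1B probes on each of the 8 arrays, as log2 relative to the array's 75th percentile, by genotype label, with a line at the mean of the 2 arrays. Open points were not well above background, which were those of ASF1B on the arrays labelled asf1a (-8.09 and -8.01) and asf1ab (-10.10 and -9.16), while ASF1A lay lower on those labelled asf1b (-1.58 and -1.53) and asf1ab (-1.49 and -1.39).

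The double mutant stood far from the other genotypes. The first principal component of 19474 genes measured on all 8 arrays held 69.9% of the variance and placed the asf1ab arrays at 57.8 and 58.3, against -24.2 to -15.6 for the other 6 arrays. The second held 13.7% and ordered wild type, the arrays labelled asf1a and those labelled asf1b. Against wild type, 3321 of 22301 genes changed on the arrays labelled asf1a, 4349 on those labelled asf1b and 12201 in asf1ab at a limma adjusted p under 0.05. Of these, 277, 523 and 2382 had a fitted change of 2-fold or more, and 126, 217 and 1739 of those were measured in both genotypes. Of 22 gene lists of at least 3 measured genes, 12, 7 and 7 passed limma's camera test at a preset correlation. With an estimated correlation, which rests on 4 residual degrees of freedom, 0 lists passed in camera in any of the 3, and 7, 5 and 3 had an unadjusted p under 0.05.

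**Figure D2:**
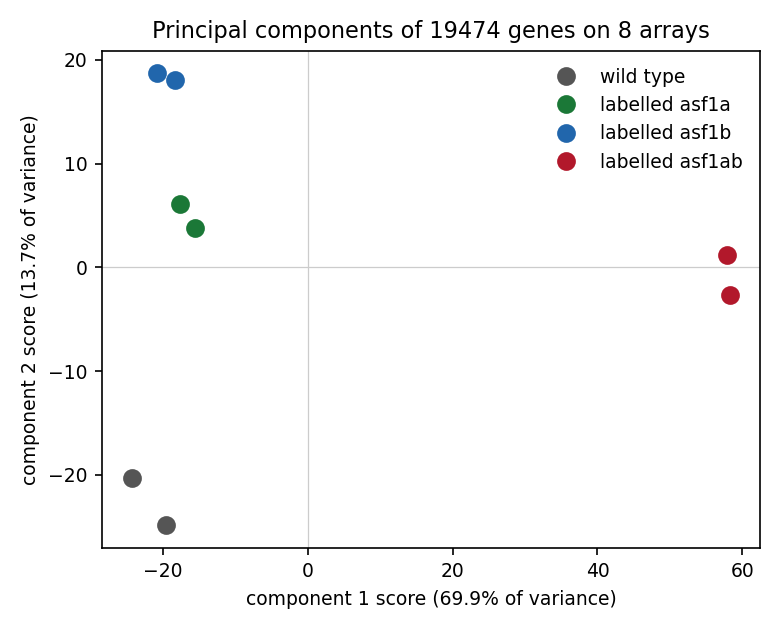
Scores of the 8 arrays on the first 2 principal components of log2 signals of genes measured on all arrays, with 1 point per array and the share of variance on each axis. The 2 asf1ab arrays lie at 57.8 and 58.3 on component 1, and the other 6 between -24.2 and -15.6.

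The comparison of the arrays labelled asf1a with wild type asks what changed in a single mutant. MRD1 (AT1G53480), described in the files as an unknown protein, was 51.6-fold higher (5.69 ± 0.07, adjusted p = 9.6e-07), and the next highest rise among genes measured on all 8 arrays was 3.77-fold, of AT5G46295. The jasmonate genes JAZ7 (1.68 ± 0.07), a repressor, JAZ5 (1.35 ± 0.17), LOX4 (1.26 ± 0.16) and JAZ10 (1.17 ± 0.07) were higher. The genes of the Casparian strip proteins CASP5 (-1.25 ± 0.11) and CASP1 (-1.08 ± 0.08) were lower. Higher by smaller amounts were the mitosis genes CYCB2;3 (0.48 ± 0.08), TPX2 (0.47 ± 0.05) and the syntaxin of the cell plate KN (0.46 ± 0.07).

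Of 23 jasmonate and wounding genes measured, 12 rose and 2 fell, or 12 and 4 adjusted over the list alone, with camera adjusted p = 0.00039, and adjusted p = 0.095 with an estimated correlation. Of 16 genes of the rapid stress response, 8 rose and 0 fell, or 12 and 2 adjusted over the list alone. TCH4 (0.84 ± 0.08) and TCH3 (0.83 ± 0.12) were among these (camera adjusted p = 5.4e-05, and adjusted p = 0.095 with an estimated correlation). The heat shock list held 25 measured genes, of which 8 rose and 1 fell, or 9 and 2 adjusted over the list alone, led by the factor HSFA2 (1.45 ± 0.09) and the chaperone HSP101 (1.27 ± 0.10), but the list as a whole did not pass (camera adjusted p = 0.059, and adjusted p = 0.36 with an estimated correlation). Among 26 mitosis genes, 11 rose and 0 fell, or 16 and 0 adjusted over the list alone (camera adjusted p = 2.6e-08, and adjusted p = 0.095 with an estimated correlation). For 27 genes of DNA replication, 4 rose and 0 fell, or 12 and 0 adjusted over the list alone. MCM6 (0.37 ± 0.09) and CDC6 (0.32 ± 0.05) were among these (camera adjusted p = 1.9e-05, and adjusted p = 0.095 with an estimated correlation). In the list of 25 core histones, 1 rose and 0 fell, or 0 and 0 adjusted over the list alone, HTA13 being the 1 that passed at 0.34 ± 0.08 (camera adjusted p = 0.045, and adjusted p = 0.66 with an estimated correlation).

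Of 20 root markers, 1 rose and 11 fell, or 2 and 13 adjusted over the list alone, with a median of -0.45 (camera adjusted p = 1.9e-05, and adjusted p = 0.095 with an estimated correlation). The nitrate transporter gene NRT2.1, on the same list, was higher by at least 1.49-fold, wild type being not well above background. Root markers stand for a tissue, and the seedlings were measured whole. Of 20 abscisic acid, drought and cold genes, 1 rose and 7 fell, or 1 and 7 adjusted over the list alone. CBF3 (-0.92 ± 0.08), HAI1 (-0.84 ± 0.07) and CBF2 (-0.64 ± 0.10) were among these (camera adjusted p = 0.0049, and adjusted p = 0.16 with an estimated correlation). The 14 glucosinolate genes gave a similar direction, since 0 rose and 3 fell, or 0 and 5 adjusted over the list alone. MYB34 (-0.55 ± 0.10) and CYP79B2 (-0.29 ± 0.07) were among these (camera adjusted p = 0.0049, and adjusted p = 0.095 with an estimated correlation). Of 17 flavonoid genes, 4 rose and 1 fell, or 9 and 2 adjusted over the list alone, with TT19 (1.09 ± 0.10) and DFR (at least 1.13 on the log2 scale) higher and MYB12 (-0.71 ± 0.11) lower (camera adjusted p = 0.0049, and adjusted p = 0.095 with an estimated correlation). In the salicylic acid list of 24 genes, 4 rose and 0 fell, or 5 and 0 adjusted over the list alone. PR5 (0.82 ± 0.08) and SARD1 (0.64 ± 0.10) were among these (camera adjusted p = 0.048, and adjusted p = 0.16 with an estimated correlation). Of 25 DNA damage genes, 2 rose and 1 fell, or 3 and 2 adjusted over the list alone, SMR7 (-0.61 ± 0.11) against COM1 (0.27 ± 0.06) and MND1 (0.27 ± 0.06) (camera adjusted p = 0.037, and adjusted p = 0.15 with an estimated correlation). Across 179 cytosolic ribosomal protein genes the median was 0.14 and 9 rose and 2 fell, or 0 and 0 adjusted over the list alone (camera adjusted p = 7e-07, and adjusted p = 0.37 with an estimated correlation). After quantile normalization the salicylic acid list no longer passed (camera adjusted p = 0.079). With the filter on all 8 arrays core histones (camera adjusted p = 0.053) and flavonoid genes (median 0.14, camera adjusted p = 0.099) did not pass.

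No shift passed in histone variants and chaperones (2 higher and 1 lower of 24, or 2 and 1 adjusted over the list alone), circadian clock genes (2 higher and 0 lower of 18, or 2 and 0 adjusted over the list alone), iron and phosphate starvation genes (3 higher and 2 lower of 14, or 3 and 3 adjusted over the list alone), auxin response genes (1 higher and 2 lower of 15, or 1 and 4 adjusted over the list alone) and transposable element genes (0 higher and 1 lower of 5, or 0 and 1 adjusted over the list alone). In limma 0 genes passed in 13 DNA methylation genes, 26 photosynthesis genes, 20 flowering genes and 8 reference genes, where 1, 1, 3 and 0 had an unadjusted p under 0.05. These 9 lists had camera adjusted p from 0.28 to 0.93, and adjusted p from 0.38 to 0.94 with an estimated correlation. The median and the mean differed in sign for the clock (-0.05 and 0.05) and iron lists (-0.05 and 0.01). For the flowering list the median (-0.00172) and the test were negative and the mean (0.02) positive. Of 2 mitochondrion-encoded genes, 0 passed in limma and 1 had an unadjusted p under 0.05, and 0 chloroplast-encoded genes had a probe that was tested.

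Most genes with the largest fitted changes were not well above background on 1 side. AT5G26700, a germin-like protein, was at least 3.41-fold higher, AT1G73510 at least 2.99-fold and the lipid transfer family member AT3G07450 at least 2.47-fold. Smaller bounds held for AT5G03090 (at least 1.89-fold), AT5G54000 (at least 1.89-fold), AT1G53260 (at least 1.55-fold), AT1G71000 (at least 1.51-fold), SESA3 (at least 1.38-fold), AT1G13540 (at least 1.31-fold) and AT1G23110 (at least 1.25-fold). AT5G44270 was not well above background in either genotype. Lower than wild type, besides ASF1B, were sks18 (at least 4.35-fold), AT1G65990 (at least 4.13-fold), NAC048 (at least 3.44-fold), LCR53 (at least 3.19-fold), AT3G49045 (at least 2.63-fold) and AT1G61920 (at least 2.38-fold). Further bounds were AT5G39640 (at least 2.33-fold), MEE39 (at most -1.14 on the log2 scale), AT1G62850 (at least 2.09-fold), RIC6 (at least 2.06-fold) and AT3G26350 (at least 1.78-fold). Among genes measured on all 8 arrays, LHT7 (1.86 ± 0.08), DTX1 (1.66 ± 0.20), DREB2C (1.64 ± 0.10) and ZAT7 (1.51 ± 0.09) were higher, and AT4G33720 (-2.00 ± 0.17), AT5G35940 (-1.61 ± 0.12), BBX30 (-1.59 ± 0.15) and AIR1 (-1.53 ± 0.10) were lower.

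In all, 1418 genes rose and 1903 fell on the arrays labelled asf1a, 2952 of them measured in both genotypes. Both genotypes were on slide 1, so these values are within 1 slide. The count was 1594 without wild type replicate 1, 1764 without wild type replicate 2, 1687 without asf1a replicate 1 and 1318 without asf1a replicate 2. Where a gene had a second probe, 96.7% of 690 called genes had the same direction on it.

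The same comparison was made for the arrays labelled asf1b, where single heat shock genes stood out. HSFA2, a heat shock transcription factor, was 8.04-fold higher than wild type (3.01 ± 0.09, adjusted p = 3.9e-05), with HSP17.8 (2.34 ± 0.09), HSP17.6C (2.27 ± 0.08) and HSP101 (2.16 ± 0.10). QQS, a small protein of starch metabolism, was 12.3-fold higher (3.61 ± 0.14, adjusted p = 8e-05). The jasmonate genes JAZ7 (2.77 ± 0.07), JAZ10 (1.84 ± 0.07), JAZ5 (1.76 ± 0.17) and LOX4 (1.54 ± 0.16) were higher here too. The zinc finger gene BBX30 (-2.40 ± 0.15) and the cytochrome P450 gene CYP71B9 (-2.57 ± 0.29) were lower.

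Of 25 heat shock genes measured, 13 rose and 0 fell, or 15 and 2 adjusted over the list alone, with a median of 0.56 (camera adjusted p = 8.3e-08, and adjusted p = 0.097 with an estimated correlation). The median was 0.35 with the normexp background. Among 23 jasmonate genes, 15 rose and 2 fell, or 15 and 2 adjusted over the list alone, with a median of 0.49 (camera adjusted p = 2.1e-06, and adjusted p = 0.097 with an estimated correlation). Of 16 rapid stress genes, 9 rose and 2 fell, or 10 and 3 adjusted over the list alone, TCH4 (1.18 ± 0.08), TCH3 (0.98 ± 0.12) and ERF6 (0.66 ± 0.06) against ERF105 (-1.35 ± 0.11) (camera adjusted p = 0.0019, and adjusted p = 0.14 with an estimated correlation). In the iron and phosphate list of 14 genes, 4 rose and 0 fell, or 9 and 0 adjusted over the list alone. MGD3 (0.93 ± 0.14) and BHLH38 (0.78 ± 0.08) were among these (camera adjusted p = 0.00037, and adjusted p = 0.14 with an estimated correlation). Of 14 glucosinolate genes, 0 rose and 6 fell, or 0 and 6 adjusted over the list alone. MYB34 (-0.72 ± 0.10), MYB29 (-0.69 ± 0.05) and MYB28 (-0.49 ± 0.07) were among these (camera adjusted p = 0.00037, and adjusted p = 0.097 with an estimated correlation). The abscisic acid, drought and cold list held 20 genes, of which 1 rose and 8 fell, or 2 and 10 adjusted over the list alone, HAI1 (-0.81 ± 0.07) and RD29B (-0.77 ± 0.10) against RD26 (0.54 ± 0.07) (camera adjusted p = 0.038, and adjusted p = 0.34 with an estimated correlation). For 26 photosynthesis genes the median was 0.14 and 1 rose and 1 fell, or 1 and 1 adjusted over the list alone (camera adjusted p = 0.032, and adjusted p = 0.75 with an estimated correlation), and under quantile normalization the direction turned, with a median of -0.02 and camera adjusted p = 0.23. The 2 that passed were PSBO1 (0.37 ± 0.07) and LHCB2.1 (-0.49 ± 0.09).

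No shift passed for DNA damage genes (2 higher and 1 lower of 25, or 2 and 1 adjusted over the list alone), DNA replication genes (1 higher and 0 lower of 27, or 1 and 0 adjusted over the list alone), core histones (0 higher and 1 lower of 25, or 0 and 0 adjusted over the list alone), histone variants and chaperones (1 higher and 1 lower of 24, or 0 and 1 adjusted over the list alone) and DNA methylation genes (1 higher and 1 lower of 13, or 1 and 1 adjusted over the list alone). The same held for salicylic acid genes (7 higher and 3 lower of 24, or 9 and 3 adjusted over the list alone), flavonoid genes (0 higher and 2 lower of 17, or 0 and 2 adjusted over the list alone), clock genes (4 higher and 1 lower of 18, or 4 and 2 adjusted over the list alone), flowering genes (2 higher and 3 lower of 20, or 2 and 3 adjusted over the list alone) and root markers (1 higher and 4 lower of 20, or 1 and 4 adjusted over the list alone). It also held for auxin genes (6 higher and 0 lower of 15, or 6 and 2 adjusted over the list alone), cytosolic ribosomal protein genes (2 higher and 7 lower of 179, or 0 and 2 adjusted over the list alone) and transposable element genes (0 higher and 1 lower of 5, or 0 and 1 adjusted over the list alone). Their tests gave camera adjusted p from 0.11 to 0.90, and adjusted p from 0.34 to 0.95 with an estimated correlation. The histone chaperone subunit FAS1 (0.41 ± 0.10) was higher and the linker histone HIS1-3 (-0.93 ± 0.07) lower. In limma 0 of 26 mitosis genes and 0 of 8 reference genes passed, where 2 of each had an unadjusted p under 0.05 (camera adjusted p from 0.49 to 0.50, and adjusted p from 0.75 to 0.78 with an estimated correlation). The median and the mean differed in sign for histone variants (0.01 and -0.00855), flavonoid (0.09 and -0.02), flowering (-0.02 and 0.02) and ribosomal protein genes (0.02 and -0.02). The salicylic acid list passed only after quantile normalization (camera adjusted p = 0.018). Root markers passed with the filter on all 8 arrays (median -0.25, camera adjusted p = 0.0054). The ribosomal median turned under quantile normalization, at -0.02. For DNA replication both were negative (-0.01 and -0.02) and the test's direction was up.

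Higher than a wild type not well above background were AT1G71000 (at least 7.58-fold), a DNAJ heat shock domain protein, ARD3 (at least 3.84-fold), AT5G05300 (at least 2.45-fold), HSP17.6A (at least 1.91-fold), AT5G28237 (at least 1.46-fold), DDF1 (at least 1.26-fold) and AT3G28510 (at least 1.14-fold). Lower, and not well above background on the arrays labelled asf1b, were sks18 (at least 27.3-fold), AT1G65990 (at least 25.9-fold), AT3G06090 (at least 20.3-fold), LCR53 (at most -4.32 on the log2 scale), AT3G49045 (at least 16.5-fold) and SAF1 (at least 15.1-fold). The others were RIC6 (at least 12.9-fold), AT4G15715 (at least 9.73-fold), AT2G44250 (at least 8.40-fold), AT1G43260 (at least 6.02-fold), AT1G68905 (at least 4.78-fold) and AT2G21420 (at least 4.52-fold). Among genes measured on all 8 arrays, RRTF1 (2.22 ± 0.15), AT1G50040 (2.02 ± 0.08) and HB4 (1.89 ± 0.10) were higher, and AT3G09870 (-2.47 ± 0.09), AT1G45904 (-2.48 ± 0.40) and AT5G37970 (-2.24 ± 0.34) lower.

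In all, 2001 genes rose and 2348 fell on the arrays labelled asf1b, and 3764 of the 4349 were measured in both genotypes. After quantile normalization the split was 2462 higher and 1498 lower, and with the normexp background 2179 and 3174. The 2 genotypes were on different slides, so their difference cannot be told apart from a difference between slides. The count was 1892 without wild type replicate 1, 2510 without wild type replicate 2, 1999 without asf1b replicate 1 and 1953 without asf1b replicate 2. A second probe gave the same direction for 92.7% of 913 called genes.

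The changes on the arrays labelled asf1a and asf1b overlapped. In both, 794 genes rose and 935 fell against wild type, and 40 moved in opposite directions, where independent lists would share 127 and 200.4 with 320.0 opposite. The odds ratio of Fisher's exact test was 20.7 for higher and 13.0 for lower genes. The correlation of changes across genes, which are not independent replicates, was 0.475 against 0.501 in 20 simulated data sets of unchanged groups with the same controls, and the covariance 0.0742 against 0.0131. The covariances of asf1ab with the arrays labelled asf1a and asf1b were 0.0890 and 0.0881, against 0.0131 and 0.0129 simulated, and the correlations 0.347 and 0.279, below the 0.502 and 0.492 simulated. Over genes measured on all 8 arrays, the correlation was 0.619 for asf1a with asf1b, 0.364 for asf1a with asf1ab and 0.300 for asf1b with asf1ab. For those genes alone no value was simulated. With asf1ab, 1972 genes changed the same way on the arrays labelled asf1a and 547 the opposite way, against 909 and 908 for independent lists. For the arrays labelled asf1b these were 2324 and 724, against 1189.9 and 1189.

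With 1 wild-type array for each of the 2 labels, no control array was shared. Fewer genes passed, and the overlap stayed above that of independent lists. The 2 wild-type arrays may come from 1 culture, so a trait of that culture would still be shared and cannot be told apart from the overlap. The arrays labelled asf1a and asf1b then shared 645 or 652 genes in the same direction, by which wild-type array went with which, against 76.5 or 92.1 for independent lists. In opposite directions they shared 34 or 36, against 73.2 or 87.3. For asf1a with asf1ab 905 or 910 had the same direction, against 407 or 335 for independent lists, and 342 or 231 the opposite, against 405 or 333. For asf1b with asf1ab these were 1130 or 1026, against 579 or 397, with 502 or 279 opposite, against 577 or 396. The arrays labelled asf1b and those of asf1ab were both on slide 2, so a difference between the slides gives them the same change and cannot be told apart from their overlap.

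The double mutant asf1ab showed the largest set of changes against wild type, with transcripts of seed storage proteins among its largest rises. CRA1, a cruciferin, was higher and measured on all 8 arrays (4.12 ± 0.11, adjusted p = 4.6e-06). The albumin SESA3 was at least 155-fold higher and SESA4 at least 74.6-fold, wild type being not well above background. The DNA repair genes GMI1 (1.81 ± 0.12) and RAD17 (1.62 ± 0.07) and the replication gene MCM6 (2.14-fold) were higher. The rapid stress genes ERF105 (-3.07 ± 0.11), ERF5 (-2.70 ± 0.09) and WRKY40 (-2.65 ± 0.08) and the cold regulator CBF3 (-1.99 ± 0.08) were lower. The flowering regulators FT (-2.09 ± 0.07) and FLC (-2.26 ± 0.09), which act in opposite ways on flowering, were both lower.

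**Figure D3:**
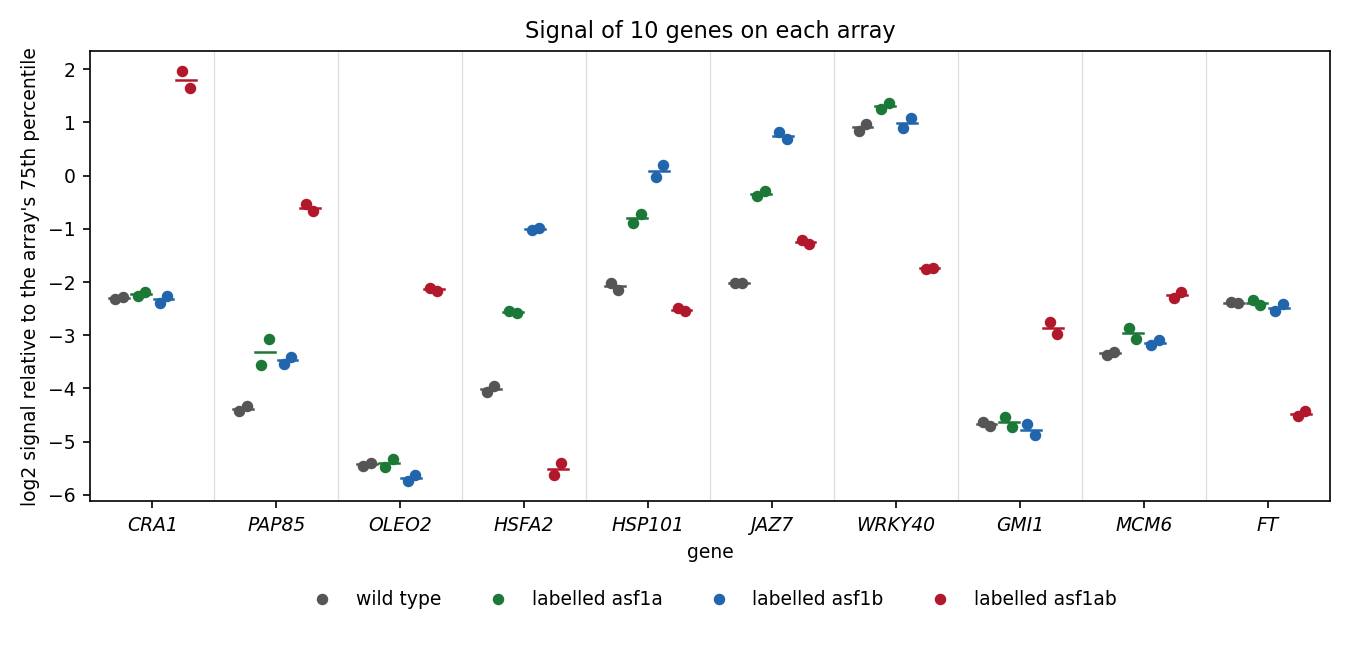
Signal of named genes on each of the 8 arrays, as log2 relative to the array's 75th percentile, with points for the arrays, a line at the mean of the 2 arrays and colours for the genotype labels; levels compare within a gene. CRA1 was 4.12 higher in asf1ab than in wild type on the log2 scale, while HSFA2 was higher on the arrays labelled asf1a (1.45) and asf1b (3.01) and lower in asf1ab (-1.51).

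Of 25 DNA damage response genes, 15 rose and 0 fell, or 15 and 0 adjusted over the list alone, with a median of 0.52 (camera adjusted p = 0.00029, and adjusted p = 0.19 with an estimated correlation). With the normexp background the median was 0.32. The plant-specific transcription factor NAC103 (1.24 ± 0.11) was among them, and so was the replication protein gene RPA1E (adjusted p = 0.023). For 27 genes of DNA replication and S phase, 18 rose and 1 fell, or 20 and 1 adjusted over the list alone, with a median of 0.33 (camera adjusted p = 0.00029, and adjusted p = 0.30 with an estimated correlation), and the polymerase subunit ICU2 (0.96 ± 0.06) and ORC3 (0.80 ± 0.06) among the higher. Among 26 mitosis genes, 12 rose and 2 fell, or 12 and 2 adjusted over the list alone, CYCA2;4 (0.65 ± 0.07) and CYCB2;3 (0.63 ± 0.08) against TES (-0.62 ± 0.07) (camera adjusted p = 0.028, and adjusted p = 0.30 with an estimated correlation), a call that quantile normalization ended (camera adjusted p = 0.11). The 25 core histones divided, as 7 rose and 7 fell, or 7 and 7 adjusted over the list alone, with HTB4 (-0.61 ± 0.08) and HTA10 (-0.50 ± 0.07) among the lower. Of 24 histone variants and chaperones, 7 rose and 5 fell, or 7 and 5 adjusted over the list alone, including UBN2 (0.97 ± 0.09), HTA8 (0.78 ± 0.08) and HTA5 (-0.74 ± 0.10). In the list of 13 DNA methylation and silencing genes, 7 rose and 2 fell, or 8 and 2 adjusted over the list alone, with the remodeller DDM1 (1.09 ± 0.14) and the histone methyltransferase ATXR5 (1.05 ± 0.09). These last 3 lists had camera adjusted p from 0.089 to 0.74, and adjusted p from 0.30 to 0.94 with an estimated correlation.

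Of 16 rapid stress genes, 4 rose and 11 fell, or 4 and 12 adjusted over the list alone, with a median of -0.82 (camera adjusted p = 0.007, and adjusted p = 0.30 with an estimated correlation). Among 20 abscisic acid, drought and cold genes, 2 rose and 12 fell, or 2 and 12 adjusted over the list alone. CBF2 (-1.69 ± 0.10) and HAI1 (-1.17 ± 0.07) were among these (camera adjusted p = 0.007, and adjusted p = 0.30 with an estimated correlation). The photosynthesis list, a marker of green tissue, held 26 genes, of which 0 rose and 9 fell, or 0 and 8 adjusted over the list alone, led by LHCB2.1 (-0.99 ± 0.09) (camera adjusted p = 0.027, and adjusted p = 0.69 with an estimated correlation). Of 20 flowering and floral identity genes, 2 rose and 11 fell, or 2 and 11 adjusted over the list alone. PI (-2.28 ± 0.11) and MAF5 (-2.14 ± 0.15) were among these (camera adjusted p = 0.025, and adjusted p = 0.33 with an estimated correlation). The heat shock list of 25 genes moved both ways, as 4 rose and 13 fell, or 4 and 13 adjusted over the list alone, with HSFB2A (-1.68 ± 0.07) and HSFA2 (-1.51 ± 0.09) against HSFA3 (1.31 ± 0.06), and missed the threshold as a set (camera adjusted p = 0.054, and adjusted p = 0.32 with an estimated correlation). With the filter on all 8 arrays it passed (median -0.38, camera adjusted p = 0.044). Of 23 jasmonate genes, 9 rose and 9 fell, or 9 and 9 adjusted over the list alone, with the defensins PDF1.3 (2.18 ± 0.09) and PDF1.2b (1.48 ± 0.07) against CORI3 (-1.31 ± 0.11) (camera adjusted p = 0.94, and adjusted p = 0.94 with an estimated correlation). For 24 salicylic acid genes, 6 rose and 9 fell, or 6 and 9 adjusted over the list alone, led by WRKY70 (-2.04 ± 0.06) and PAD3 (-1.18 ± 0.14) (camera adjusted p = 0.57, and adjusted p = 0.69 with an estimated correlation).

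Of 18 circadian clock genes, 6 rose and 9 fell, or 6 and 9 adjusted over the list alone, the morning genes LHY (-1.50 ± 0.11), PRR9 (-1.39 ± 0.11) and RVE1 (-1.32 ± 0.06) against PRR5 (1.06 ± 0.09). The labels do not give the hour of harvest, so another hour cannot be told apart from the genotype for transcripts that vary over the day. Among 14 glucosinolate genes, 2 rose and 8 fell, or 2 and 8 adjusted over the list alone, with MYB29 (-0.95 ± 0.05) and CYP83A1 (-0.87 ± 0.06). In the flavonoid list of 17 genes, 10 rose and 4 fell, or 10 and 4 adjusted over the list alone, with CHS (1.54 ± 0.10), DFR at least 3.47-fold higher, and PAP1 (-1.52 ± 0.10). Iron genes BHLH38 (2.25 ± 0.08), BHLH100 (1.96 ± 0.12) and BHLH39 (1.23 ± 0.07) rose, and on that list of 14 genes 6 rose and 4 fell, or 6 and 4 adjusted over the list alone, with a median of -0.03, a mean of 0.32 and a test directed up. Root markers moved both ways, since of 20 genes 7 rose and 6 fell, or 7 and 6 adjusted over the list alone, WER (0.80 ± 0.12) against CASP5 (-1.47 ± 0.11). Of 15 auxin response genes, 6 rose and 3 fell, or 6 and 3 adjusted over the list alone, with a median of -0.00617, a mean of -0.11 and a test directed up. Of 8 reference genes often used to scale such data, 0 rose and 5 fell, or 0 and 5 adjusted over the list alone, led by ACT8 (-0.67 ± 0.15) and ACT2 (-0.52 ± 0.10). For 179 cytosolic ribosomal protein genes, 48 rose and 14 fell, or 44 and 12 adjusted over the list alone. Of 5 transposable element genes, 2 rose and 1 fell, or 2 and 1 adjusted over the list alone. These 9 lists had camera adjusted p from 0.061 to 0.74, and adjusted p from 0.30 to 0.78 with an estimated correlation. After quantile normalization the photosynthesis list no longer passed (median -0.04, camera adjusted p = 0.28), and the ribosomal protein list did (camera adjusted p = 0.0017), as it did with the filter on all 8 arrays (camera adjusted p = 0.045). Of 2 mitochondrion-encoded genes, ATMG00910 was higher (1.34 ± 0.31, adjusted p = 0.011), with 1 wild-type array not well above background.

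**Figure D4:**
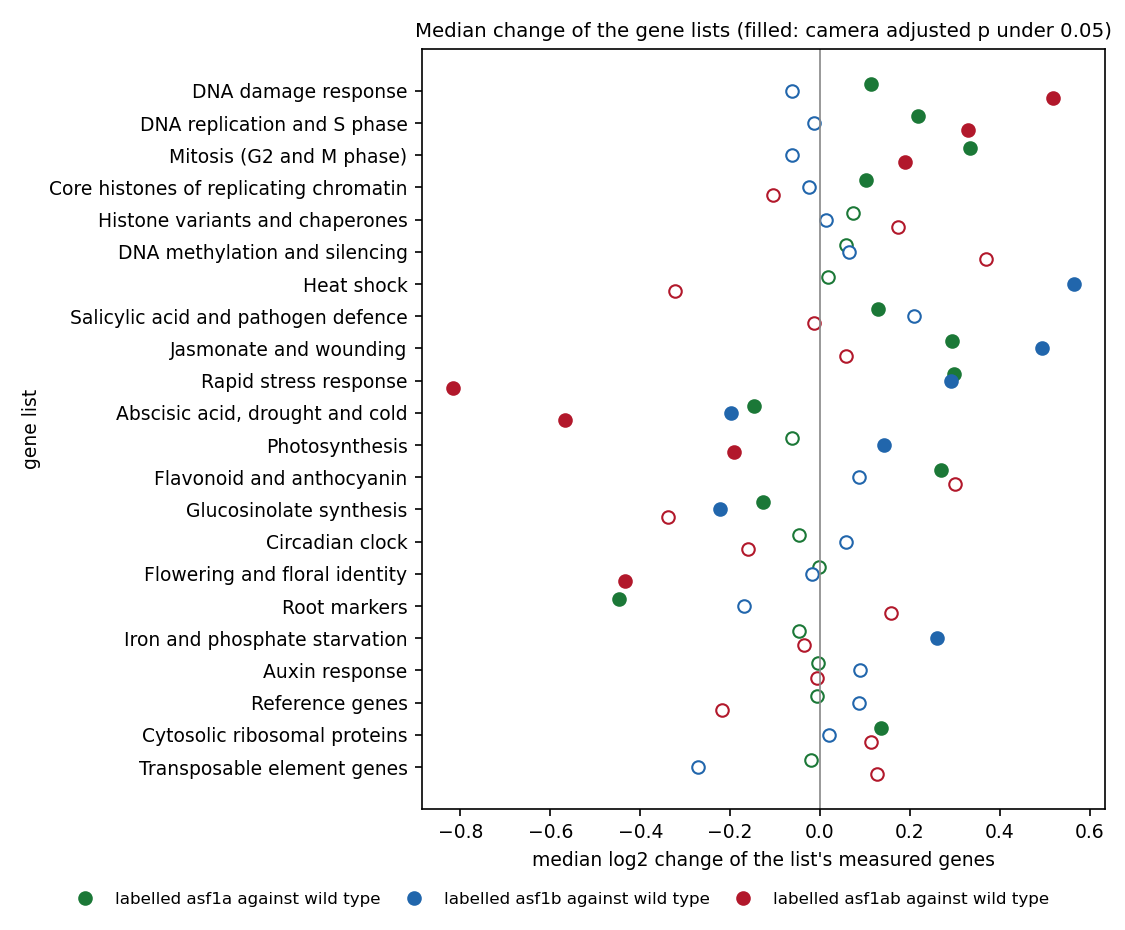
Median log2 change of the measured genes of each list of at least 3 genes, for each mutant label against wild type, with filled points for lists past the camera threshold at a preset correlation. For the rapid stress list the medians were 0.30 and 0.29 on the arrays labelled asf1a and asf1b and -0.82 in asf1ab, and that of photosynthesis on the arrays labelled asf1b (0.14) turned under quantile normalization.

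Further genes higher in asf1ab were CRU2 (at least 33.5-fold), SESA2 (at least 19.8-fold), SESA1 (at least 16.0-fold) and ATS1 (at least 14.4-fold), with CRU3 (5.44 ± 0.48), PAP85 (3.78 ± 0.16) and OLEO2 (3.29 ± 0.08), which encode storage or oil body proteins of seeds. AT2G05580 (at least 24.1-fold), AT1G47540 (at least 11.3-fold), AT1G65090 (at least 7.58-fold) and AT5G53700 (at least 7.16-fold) were also higher than a wild type not well above background. MRD1 (4.92 ± 0.07) and QQS (3.32 ± 0.14) were higher too, as were AT1G22980 (4.07 ± 0.08), AT5G60610 (3.94 ± 0.12), HEMA3 (3.39 ± 0.14) and AT3G28500 (3.31 ± 0.10). Lower and measured on all 8 arrays were AT4G07820 (-5.76 ± 0.12), AT5G56990 (-4.77 ± 0.11), BBX30 (-4.74 ± 0.15), AT1G24147 (-4.24 ± 0.14), RTL2 (-4.15 ± 0.06) and SAG29 (-3.88 ± 0.07). Not well above background in asf1ab, and lower, were sks18 (at least 36.3-fold), AT1G65990 (at least 34.4-fold), the senescence protease gene SAG12 (at least 31.7-fold), FRO5 (at least 32.1-fold), LCR53 (at least 26.6-fold) and AT3G06090 (at least 27.0-fold). The last of these were AT3G49045 (at least 22.0-fold), AT3G26860 (at most -4.19 on the log2 scale) and RIC6 (at least 17.2-fold), and MYB19 was not well above background in either genotype.

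In asf1ab 6088 genes rose and 6113 fell against wild type, or 6624 and 5530 after quantile normalization and 5544 and 7037 with the normexp background. Of the first, 655 and 1084 were measured in both genotypes and changed by 2-fold or more. A second probe gave the same direction for 91.2% of 3004 called genes. The genotypes were on different slides, so this comparison alone cannot be told apart from a difference between slides, and the comparison with the arrays labelled asf1b is the one within slide 2.

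Within slide 2, asf1ab was compared with the arrays labelled asf1b, which asks what the second mutation added. Storage transcripts stood out again, with SESA3 at least 896-fold, SESA4 at least 419-fold, CRU2 at least 194-fold and SESA1 at least 92.8-fold higher, and CRA1 higher (4.13 ± 0.11, adjusted p = 4.3e-06). AT4G18900, a WD-40 repeat protein, was at least 34.9-fold higher. The heat shock genes HSFA2 (-4.51 ± 0.09), HSP17.8 (-2.79 ± 0.09) and HSP101 (-2.61 ± 0.10) were lower. Lower also were AT4G07820 (-5.24 ± 0.12), AT1G24147 (-4.98 ± 0.14), AT5G55150 (-4.92 ± 0.09) and SAG12, the last by at least 20.3-fold.

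Of 25 DNA damage genes, 20 rose and 0 fell, or 21 and 0 adjusted over the list alone. PARP2 (1.49 ± 0.09) and GMI1 (1.92 ± 0.12) were among these (camera adjusted p = 5.9e-06, and adjusted p = 0.081 with an estimated correlation). Among 25 heat shock genes, 2 rose and 19 fell, or 2 and 19 adjusted over the list alone, with a median of -0.93 (camera adjusted p = 2.5e-06, and adjusted p = 0.081 with an estimated correlation). Of 16 rapid stress genes, 2 rose and 13 fell, or 2 and 13 adjusted over the list alone, with a median of -1.26 (camera adjusted p = 1.6e-05, and adjusted p = 0.081 with an estimated correlation). In the jasmonate list of 23 genes, 3 rose and 16 fell, or 3 and 16 adjusted over the list alone (camera adjusted p = 0.00044, and adjusted p = 0.081 with an estimated correlation). For 26 photosynthesis genes, 0 rose and 19 fell, or 0 and 19 adjusted over the list alone, with a median of -0.32 and PSBO1 (-0.65 ± 0.07) as an example (camera adjusted p = 0.00044, and adjusted p = 0.42 with an estimated correlation). Quantile normalization ended this call (median -0.02, camera adjusted p = 0.64). DNA replication genes numbered 27, and 20 rose and 2 fell, or 20 and 3 adjusted over the list alone (camera adjusted p = 0.00044, and adjusted p = 0.18 with an estimated correlation). Of 26 mitosis genes, 14 rose and 1 fell, or 14 and 2 adjusted over the list alone (camera adjusted p = 0.01, and adjusted p = 0.24 with an estimated correlation). The lists of flowering (3 higher and 13 lower of 20, or 4 and 13 adjusted over the list alone), abscisic acid (5 higher and 14 lower of 20, or 5 and 14 adjusted over the list alone), salicylic acid (3 higher and 12 lower of 24, or 3 and 12 adjusted over the list alone) and reference genes (0 higher and 5 lower of 8, or 0 and 6 adjusted over the list alone) were shifted down. Their camera tests gave adjusted p = 0.0086, 0.031, 0.041 and 0.031. With an estimated correlation their adjusted p = 0.26, 0.25, 0.24 and 0.26. After quantile normalization the abscisic acid and reference lists no longer passed (camera adjusted p = 0.068 and 0.28), while histone variants and ribosomal proteins did (camera adjusted p = 0.029 and 2.9e-05). The filter on all 8 arrays ended the call of salicylic acid (camera adjusted p = 0.06). The other 11 lists had camera adjusted p from 0.079 to 0.80, and adjusted p from 0.25 to 0.91 with an estimated correlation, and the auxin list had a median of 0.00549 and a mean of -0.21. In all, 6418 genes rose and 5998 fell, or 5767 and 6718 with median centring. A second probe gave the same direction for 90% of 3070 called genes, and for 255 of 260 called with 2-fold or more.

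Against the arrays labelled asf1a, 5936 genes rose and 5525 fell in asf1ab, or 5476 and 5956 with median centring. SESA4 was at least 68.8-fold and CRU2 at least 30.9-fold higher, and SESA3 (6.81 ± 0.43), CRU3 (6.76 ± 0.48) and QQS (4.07 ± 0.14) were higher, SESA3 and CRU3 with 1 asf1a array not well above background. Lower were SAG12 (at least 59.5-fold), AT1G73510 (at least 23.0-fold), AT5G48550 (at most -4.19 on the log2 scale), AT3G03350 (at least 17.3-fold) and AT1G24147 (-5.24 ± 0.14). Of 16 rapid stress genes, 1 rose and 13 fell, or 1 and 13 adjusted over the list alone (camera adjusted p = 2.2e-05, and adjusted p = 0.16 with an estimated correlation). Of 20 root markers, 15 rose and 2 fell, or 15 and 2 adjusted over the list alone. COBL9 (1.13 ± 0.13) and PHT1;1 (1.34 ± 0.17) were among these (camera adjusted p = 0.0047, and adjusted p = 0.31 with an estimated correlation). In the heat shock list of 25 genes, 4 rose and 14 fell, or 4 and 16 adjusted over the list alone (camera adjusted p = 0.0021, and adjusted p = 0.27 with an estimated correlation), and among 23 jasmonate genes, 3 rose and 13 fell, or 4 and 13 adjusted over the list alone (camera adjusted p = 0.0087, and adjusted p = 0.21 with an estimated correlation). Of 25 DNA damage genes, 14 rose and 1 fell, or 14 and 1 adjusted over the list alone (camera adjusted p = 0.0021, and adjusted p = 0.16 with an estimated correlation). In the flowering list of 20 genes, 2 rose and 12 fell, or 2 and 12 adjusted over the list alone (camera adjusted p = 0.0062, and adjusted p = 0.33 with an estimated correlation). Of 27 DNA replication genes, 13 rose and 3 fell, or 13 and 3 adjusted over the list alone (camera adjusted p = 0.043, and adjusted p = 0.33 with an estimated correlation), and of 20 abscisic acid genes, 4 rose and 11 fell, or 4 and 11 adjusted over the list alone (camera adjusted p = 0.043, and adjusted p = 0.33 with an estimated correlation). Quantile normalization ended both calls (camera adjusted p = 0.14 and 0.073), and so did the filter on all 8 arrays for abscisic acid (camera adjusted p = 0.057). The other 14 lists had camera adjusted p from 0.064 to 0.67, and adjusted p from 0.33 to 0.85 with an estimated correlation, and the mean had the other sign than the median for auxin (0.09 and -0.000745) and ribosomal protein genes (-0.02 and 0.000157). The genotypes were on different slides, which cannot be told apart from the difference between them.

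The non-additive contrast asks whether the change in asf1ab differed from the sum of the changes on the arrays labelled asf1a and asf1b, and an additive difference between the slides cancels in it. It passed for 9201 genes, 4875 above the sum and 4326 below it, whichever single mutant each label belongs to. With median centring these were 4216 and 5098, so which side held more genes depended on the scaling. HSFA2 lay below the sum, at -5.96 ± 0.12 relative to it on the log2 scale (adjusted p = 4.9e-06), and AT1G24147 (-5.98 ± 0.19), AT4G08555 (-5.56 ± 0.10), AT5G55150 (-5.52 ± 0.12) and UGT73C1 (-5.43 ± 0.11) were below it too. Above it, and measured on all 8 arrays, were AT3G19430 (4.08 ± 0.31), CRA1 (4.05 ± 0.16), AT1G22980 (4.02 ± 0.12), AT5G60610 (3.86 ± 0.16) and AT3G28500 (3.67 ± 0.14). CRU2, SESA4, SESA3, SESA1 and AT2G43960 also lay above the sum and AT1G71000 and SAG12 below it, without a value here because they were not measured in every genotype. Of 16 rapid stress genes, 0 lay above and 15 below the sum, and the same when adjusted over the list alone (camera adjusted p = 5.5e-09, and adjusted p = 0.072 with an estimated correlation). The same counts were 2 and 17 of 23 for jasmonate (camera adjusted p = 2e-05, and adjusted p = 0.072 with an estimated correlation) and 0 and 16 of 25 for heat shock genes (camera adjusted p = 4e-07, and adjusted p = 0.072 with an estimated correlation). For DNA damage genes they were 11 and 1 of 25 (camera adjusted p = 0.00065, and adjusted p = 0.072 with an estimated correlation), and for root markers 11 and 0 of 20 (camera adjusted p = 0.0012, and adjusted p = 0.20 with an estimated correlation).

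Adjusted over the list alone, 4 jasmonate genes lay above and 17 below the sum, 0 and 18 heat shock genes, 13 and 1 DNA damage genes, and 11 and 0 root markers. The lists of photosynthesis (camera adjusted p = 0.005, and adjusted p = 0.55 with an estimated correlation), flowering (camera adjusted p = 0.0057, and adjusted p = 0.36 with an estimated correlation), salicylic acid (camera adjusted p = 0.0075, and adjusted p = 0.14 with an estimated correlation) and clock genes (camera adjusted p = 0.0081, and adjusted p = 0.20 with an estimated correlation) were shifted below it as sets. Quantile normalization ended the calls of photosynthesis (median -0.01, camera adjusted p = 0.71) and clock genes (median -0.12, camera adjusted p = 0.10). The other 13 lists had camera adjusted p from 0.07 to 0.59, and adjusted p from 0.37 to 0.78 with an estimated correlation. For ribosomal protein genes the median (-0.05) and the test were negative and the mean (0.02) positive, and the median was 0.11 under quantile normalization.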

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

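The tests of the labels and of the slides were chosen after their results were seen, and those of seeds, embryo regulators and harvest time after the patterns they address had been seen but before their own results. The change of the double mutant differed from the sum of the single-mutant changes in a test of the difference itself for 9201 genes. By the same contrast the list medians on the log2 scale were 0.55 for DNA damage, 0.66 for root markers, -0.87 for heat shock, -0.48 for salicylic acid, -1.03 for jasmonate, -1.38 for rapid stress, -0.27 for photosynthesis, -0.25 for the clock and -0.54 for flowering. All 9 passed in camera at the preset correlation and none with an estimated one (adjusted p from 0.072 to 0.55). After quantile normalization photosynthesis and the clock no longer passed (median -0.01 and -0.12, camera adjusted p = 0.71 and 0.10) and the DNA damage median was 0.35. With the normexp background the medians shrank to 0.36 for DNA damage, 0.39 for root markers, -0.55 for heat shock and -0.28 for salicylic acid. Genes above the sum were AT3G19430 (4.08), CRA1 (4.05), AT1G22980 (4.02), AT5G60610 (3.86) and AT3G28500 (3.67). Genes below it were AT1G24147 (-5.98), HSFA2 (-5.96), AT4G08555 (-5.56), AT5G55150 (-5.52) and UGT73C1 (-5.43).

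ASF1B was low on the arrays labelled asf1a and ASF1A on those labelled asf1b. A single mislabelled array is argued against. The gene low in a single mutant differed by at most 0.0774 on the log2 scale between its 2 arrays. That value is of ASF1B, which was not well above background on either array labelled asf1a. ASF1A, which was measured, was at -1.58 and -1.53 on those labelled asf1b. An exchange of the labels, or of the 2 gene names, stays open: ASF1A was low on the arrays labelled asf1b (-1.57), but that is part of the pattern and no separate evidence. That each mutation may lower the other gene and spare its own probe stays open too, because ASF1A in asf1ab against asf1a (-1.48) is what both explanations need. For ASF1A a difference between the slides stays open as well, since this gene was low on every array of slide 2 and on none of slide 1. For ASF1B an additive slide difference is argued against, as it was at least 31.2-fold lower on the arrays labelled asf1a within slide 1. Where the mutations lie is not given in the sources used here.

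Seed storage transcripts were high in asf1ab. An additive slide difference is argued against, as their median log2 difference between asf1ab and asf1b, on 1 slide, was 5.30 over 14 genes. Dim genes were taken at their bounds, and the genes ran from 1.36 to 9.81. The scaled median absolute deviation over the square root of the number of genes was 0.59, a measure that takes genes as independent. Seeds that had not germinated, or had just done so, could bring such transcripts, and the median of 17 late embryogenesis abundant genes was 1.07 with a spread of 0.56, between the bounds set for and against. On the arrays labelled asf1b 8 of these genes were lower than in wild type and 0 higher, which raises that median, and across the slides it was 0.80 against wild type and 0.75 against asf1a. Of the embryo regulators LEC1, LEC2, FUS3 and ABI3 the highest past the threshold was FUS3, 1.36 higher in asf1ab than in asf1b (limma adjusted p = 0.00031), as higher embryo regulators would need, while ABI3 (1.94, limma adjusted p = 0.088) did not pass and LEC2 was lower (-0.73). Both stay open, since seeds may carry such regulators too.

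The jasmonate and rapid stress lists passed as higher in camera at the preset correlation on the arrays labelled asf1a and asf1b. With an estimated correlation neither passed (adjusted p = 0.095 for both in asf1a, and 0.097 and 0.14 in asf1b). The heat shock list passed in asf1b (camera adjusted p = 8.3e-08, and 0.097 with an estimated correlation) and missed the threshold in asf1a (camera adjusted p = 0.059), and the labels were not tested against each other. For asf1a an additive difference between the slides is argued against, since 28 of 64 members were higher and 3 lower within slide 1. For asf1b it cannot be told apart from the genotype. In asf1ab, on the slide of asf1b, 17 members were higher and 33 lower than in wild type, but the double mutation could lower them itself. Harvest at another time of day stays open, as evening minus morning clock genes moved by 0.31 in asf1a and 0.43 in asf1b. Both were short of the 0.5 set beforehand, in asf1b by less than the standard error (0.0735, with genes taken as independent).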

How the results depend on the processing

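The counts of changed genes below are in the order asf1a, asf1b and asf1ab against wild type, asf1ab against asf1a and against asf1b, and the non-additive contrast. They were 3271, 3960, 12154, 11366, 11417 and 8150 with quantile normalization, 3208, 5353, 12581, 11994, 12300 and 8973 with the normexp background and 3273, 3960, 12147, 11371, 11414 and 8155 with the deposited table, all within 1.5 times the reported counts. Median centring, a filter on all 8 arrays, the mean of a gene's probes and the intensity trend also stayed within that. Of 216 tests of called lists under alternatives 147 kept the call, 68 lost it and 1 reversed, and 7 of 312 tests of other lists gained one. For called named genes 7472 of 8112 kept it, 640 lost it and 0 reversed, and 7 of 156 others gained one. A 2-fold minimum left 277, 523, 2382, 2106, 2297 and 2547 genes by its construction, and the shared calls were 94 for asf1a and asf1b, 129 for asf1a and asf1ab and 174 for asf1b and asf1ab. With separate wild-type arrays, chosen after the data were seen, they were 645 or 652, 905 or 910, and 1130 or 1026. Without the filter on dim probes asf1b against wild type gave 7418, 2119 higher and 5299 lower, and the cause was not tested. The splits of asf1ab became 5912 and 9180 against wild type, 5775 and 8595 against asf1a and 6207 and 6769 against asf1b. That of asf1b, 2001 higher and 2348 lower in the reported fit, became 2462 and 1498 with quantile normalization and 2463 and 1497 with the deposited table, and 2387 and 1959 with median centring. With a common detection floor it was 1922 and 1842, and with the normexp background, which kept the side, 2179 and 3174. The asf1ab splits turned too, to 6624 and 5530 against wild type with quantile normalization. With median centring they were 5476 and 5956 against asf1a, 5767 and 6718 against asf1b and 4216 and 5098 in the non-additive contrast. Against asf1a and asf1b they were 5589 and 6405, and 5871 and 6429, with the normexp background. With the filter on all 8 arrays these were 5387 and 5424, and 5746 and 5961. With an estimated correlation 0 lists passed in camera in each contrast, and 7, 5, 3, 4, 5 and 5 had an unadjusted p under 0.05. Photosynthesis in asf1b against wild type was the 1 list that reversed, to a median of -0.0243 with quantile normalization (adjusted p = 0.23), and the cause was not tested. Among all called genes, 59, 37 and 36 passed in the opposite direction with quantile normalization or the deposited table in asf1b and asf1ab against wild type and asf1ab against asf1a, and 1 in the non-additive contrast. With the mean of a gene's probes these were 18, 80, 72 and 5, and 18 in asf1ab against asf1b. With the normexp background 11, 6 and 6 reversed in asf1ab against wild type, asf1a and asf1b, and with a common detection floor 2 in the non-additive contrast. No scaling shifted the median of all genes by more than 0.1 on the log2 scale.

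Leaving out each array in turn gave 1318 to 3279, 1892 to 4459, 9351 to 11790, 8072 to 11152, 9691 to 12092 and 6418 to 8797 genes, where a lone array was assumed to vary like the other genotypes. Only asf1a and asf1b against wild type moved by over 1.5 times. For asf1a this was without wild type replicate 1 (1594), wild type replicate 2 (1764), asf1a replicate 1 (1687) and asf1a replicate 2 (1318). For asf1b it was without wild type replicate 1 (1892), wild type replicate 2 (2510), asf1b replicate 1 (1999) and asf1b replicate 2 (1953). The compared genotypes alone gave 2464, 2917, 10447, 10509 and 11219, and this was not run for the non-additive contrast, which needs all 4. With the slide as a block, asf1a against wild type, asf1ab against asf1b and the non-additive contrast gave 3321, 12416 and 9201, the same by construction. The other 3 contrasts cross the slides, so this was not run for them, nor was a random block, whose correlation cannot be estimated with each genotype on 1 slide. The scan is the same as the slide and was not run.

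With the replicate number as a block (replicate block) the counts were 3305, 4298, 12382, 11688, 12591 and 9380, and no list changed its call. Over tested genes the deviations of same-numbered arrays correlated at 0.04, 0.05, -0.06, 0.02, 0.01 and 0.28 for wild type with asf1a, asf1b and asf1ab, asf1a with asf1b and asf1ab, and asf1b with asf1ab. Over genes measured on all 8 arrays the last was 0.48 and the others lay from -0.12 to 0.16, with both signs, so the numbers were not taken to pair all arrays. Crossing the numbers of asf1ab and wild type gave 9946 paired calls against 8882 uncrossed. Signal over background limits the dim genes: with a common detection floor the counts were 3326, 3764, 11265, 10530, 11313 and 8433. The floor, the crossing and the filter on all 8 arrays for lists and overlaps were chosen after the data were seen.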

Other observations

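The test of neighbouring genes was chosen before its result was seen, while its wider sets, the 4 seed and embryo lists, and the genes MRD1, HEI10, QQS and AT3G30740 as named here, were chosen after the storage transcripts and those genes had been seen. The other loci near MRD1 were chosen after it had been seen. Of 14 genes of seed storage and oil body proteins, 14 were higher in asf1ab than in wild type, 14 than on the arrays labelled asf1a and 14 than on those labelled asf1b. With dim genes at their bounds, the median log2 changes were 4.06, 3.97 and 5.30. Some of these genes had been seen among the largest rises before the list was drawn up, so camera's p for it is not given, as that test could hardly have failed. Of 17 late embryogenesis abundant genes, 11 were higher and 4 lower in asf1ab than on the arrays labelled asf1b (camera adjusted p = 0.0054, and adjusted p = 0.20 with an estimated correlation). Against wild type 9 were higher and 5 lower, and the list did not pass (camera adjusted p = 0.055, and adjusted p = 0.32 with an estimated correlation). EM1 (3.71 ± 0.11), AT2G42560 (3.19 ± 0.31) and AT5G44310 (14.0-fold) were higher than on the arrays labelled asf1b, and M17 (-2.20 ± 0.19) and LEA7 (-0.81 ± 0.09) lower.

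Of 9 embryo regulators, 6 were higher and 1 lower in asf1ab than on the arrays labelled asf1b (camera adjusted p = 0.0089, and adjusted p = 0.096 with an estimated correlation). ABI5 (1.42 ± 0.08), NF-YB6 (1.43 ± 0.17) and FUS3 (1.36 ± 0.13) were higher and LEC2 (-0.73 ± 0.08) lower. Of 7 repressors of the embryo state, 4 were higher, among them CLF (0.50 ± 0.06) (camera adjusted p = 0.029, and adjusted p = 0.22 with an estimated correlation). Across the slides this list passed against wild type (camera adjusted p = 0.045) and did not pass against asf1a (camera adjusted p = 0.072). On the arrays labelled asf1b, 8 late embryogenesis abundant genes were lower than in wild type and 0 higher in limma (camera adjusted p = 0.00028, and adjusted p = 0.32 with an estimated correlation). Evening minus morning clock genes moved by 1.62 on the log2 scale in asf1ab against wild type, with means of 0.58 for evening and -1.03 for morning genes. Against asf1b, within slide 2, the difference was 1.18, with means of 0.07 and -1.11, so it lay in the fall of the morning genes. The standard error of each difference was 0.0735, with genes taken as independent. Both differences lay past the 0.5 set beforehand for the single mutants. The hour of harvest is not given, so another hour for asf1ab cannot be told apart from its genotype.

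Some transcripts followed 1 single-mutant label into the double mutant. MRD1 was at 5.69 ± 0.07 relative to wild type on the arrays labelled asf1a, 0.46 ± 0.07 on those labelled asf1b and 4.92 ± 0.07 in asf1ab, and the next locus, HEI10, was at 1.18 ± 0.11, 0.01 ± 0.11 and 1.95 ± 0.11. The loci on either side of this pair, MSL4 (-0.21, -0.04 and -0.21) and MUM4 (-0.01, -0.07 and -0.53), did not rise with it. For AT1G53260, where wild type was not well above background, the bounds were at least 0.63 in asf1a and 2.09 in asf1ab. Its bound in asf1b (-1.60) showed no rise. QQS was at -0.75 ± 0.14, 3.61 ± 0.14 and 3.32 ± 0.14, and the nearby locus AT3G30740 at 0.04 ± 0.13, -1.15 ± 0.13 and -1.42 ± 0.13. With changes of at least 1 on the log2 scale matched within 0.5, 16 genes followed asf1a (2 higher and 14 lower) and 24 asf1b (4 higher and 20 lower). MRD1, HEI10 and QQS are not in these sets, so a tolerance of 1 was added, which holds them, with 44 and 81 genes. At this tolerance a gene may change by up to 1 under the other label too, as bZIP5 did (-0.94 in asf1a and -1.07 in asf1b). The wider sets thus also hold genes that changed alike under both labels. The arrays labelled asf1b and those of asf1ab were on slide 2, and wild type and asf1a on slide 1. A difference between the slides gives the same pattern, so the genes that followed asf1b, QQS among them, cannot be told apart from it. Genes inherited together with a mutation would lie near it, and so near each other. Only nearness to another gene of the set was counted, and the distance to ASF1A or ASF1B was not measured. The sets of asf1b hold ASF1A itself, and those of asf1a hold AT5G38005, whose locus number is close to that of ASF1B. The wider set of asf1b holds AT5G37970, whose locus number is close to that of ASF1B too. It was at -0.63 in asf1a, -2.24 in asf1b and -2.73 in asf1ab. In the wider sets 20 of 125 lay within 20 tested loci of another of their set, 5 with asf1a and 15 with asf1b, against at most 8 and 20 in 95% of 1000 random draws. In the narrower sets these were 2 and 0, against 2 and 4. Linkage of most of a set is thus argued against, but a few linked genes would not show in such a count. In the wider sets, genes that changed under both labels dilute it further. The ASF1A probe is on chromosome 1 and the ASF1B probe on chromosome 5, and QQS and AT3G30740 are on neither. This argues against linkage of that pair to either gene. MRD1 and HEI10 are on the chromosome of ASF1A, so this pair may still be linked to a mutation there. The arrays labelled asf1a, which it followed, were low in ASF1B and not in ASF1A.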
